A study of Mus musculus with 14 samples.

How the data were processed

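RNA was measured by high-throughput sequencing in 14 mouse libraries. Lewis lung carcinoma (LLC) cells, a mouse lung tumor line, had been placed in the flanks of wild-type (WT) mice and of p110g-/- mice, which lack PI3K gamma, the catalytic subunit encoded by Pik3cg, and the tumors were taken on day 14. The libraries were made from pieces of whole tumor (30 mg; 3 WT and 3 p110g-/-) or from CD11b+Gr1- cells sorted out of tumors (1000000 cells; 4 WT and 4 p110g-/-), which the labels name tumor-associated macrophages (TAM). The labels give C57BL/6 as the strain of both genotypes. Nothing in the labels says that each library came from a separate animal, so the p-values measure the spread between these samples, which may be technical.

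Per the submitters' processing notes, Bowtie2, DESeq and the mouse build mm9 were used, with no versions or order. The gene counter, the annotation and the formula of the normalization are not given in the sources used here. The authors deposited a table for the TAM and a table for the whole tumors, each with the same 12924 genes. The deposited values are a score, that is, whole numbers made by scaling each library's gene counts by a single factor and rounding, and are called normalized counts here. This was read from the values. Some libraries skip whole numbers at a regular period, as rounding after multiplication by a factor above 1 does. A step finder that estimates how many units a read is worth was tested on simulated data and recovered the step within 1% in 14 of 14 libraries. It gave 32.1 to 44.6 M estimated reads in genes for the whole tumors and 19.7 to 40.7 M for the TAM, so 3 reads correspond to 1.79 to 5.81 normalized counts, counting error only. Each of the authors' deposited tables also holds a value from 0 to 1 per gene, headed pp, whose meaning is not given in the sources used here. Gene identifiers and symbols were used as the tables give them, except that 21 symbols turned into dates were renamed by their identifier. The reference gene table, of another build (GRCm38.p6), held 12840 of the identifiers and was used only for names and for which genes neighbour each other, so no coordinates are given. How reads shared by near-identical genes were counted is not given in the sources used here. The values of Lyz1 and Lyz2, Tgtp1 and Tgtp2, H60b, Raet1e, Apol9b, Ly6c2 and the H2-Q and H2-T genes are uncertain for that reason.

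The planned test was a count model. Because the deposited values are not raw counts, limma 3.58.1 (R 4.3.3) was used in its place, on log2(normalized count + 1) with a mean-dependent prior on the spread. Fold changes are on that scale, which understates the change of low genes. A gene was tested when at least as many libraries as the smaller group holds (4 TAM, 3 whole tumor) reached 10 normalized counts. P-values were adjusted by the Benjamini-Hochberg method, all tests were two-sided, and a gene is said to have risen or fallen when its adjusted p was below 0.05. The genotypes were compared within each table. The difference of the genotype effects was fitted over all 14 libraries as the effect in TAM minus the effect in whole tumor, a difference of within-table differences. It had been planned for raw counts only and was run on the normalized counts. A test of TAM against whole tumor had the same condition, and only levels are given for it. The similarity of the genotype effects is a correlation across genes, which are not independent replicates, with an exact two-sided permutation of the 70 labelings of the TAM libraries. It used log2(normalized count + 2) and the genes that reached 10 normalized counts in at least 3 libraries of each table. Counts per 1000000 (CPM), used in the naming rule below, were computed from the column totals of the normalized counts.

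The labels number the libraries 1 to 4 in both TAM groups without saying what a number marks. Over 11281 genes, the deviations of same-numbered TAM libraries from their group means correlated at 0.857, 0.532, 0.853 and 0.762, so same-numbered TAM libraries were alike. The WT and p110g-/- libraries numbered 4 each correlated more strongly with number 3 of the other genotype. A coarser structure by number therefore cannot be told apart from 4 pairs, and a pair below means libraries of the same number. A fit with the number as a block is an alternative, and its value stands beside a TAM result where it changes the call or moves a count by more than 1.5 times.

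Before the data were examined, 32 gene lists were fixed. They cover PI3K class I subunits, MHC class I presentation, MHC class II presentation, immune-stimulating mediators, immune-suppressive and alternative activation genes, the type I interferon response, the interferon-gamma response, NF-kB inflammatory targets, and chemokines for monocytes and neutrophils. Lists of markers cover macrophages, monocytes, dendritic cells, neutrophils, T cells, cytotoxic and NK cells, B and plasma cells, mast cells and basophils, endothelium, fibroblasts and matrix, carcinoma epithelium, keratinocytes, skeletal muscle, adipocytes and erythroid cells. The others are proliferation, hypoxia and glycolysis, angiogenic factors, immediate-early and dissociation stress genes, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis, and lysosome and lipid handling. Each list with at least 3 tested members was tested with limma's camera against the other genes, adjusted over the lists. The preset inter-gene correlation was 0.01, and the test was repeated with an estimated correlation. The deposited values held 3 of 13 keratinocyte, 5 of 11 adipocyte, 5 of 11 erythroid and 7 of 18 skeletal muscle genes. They held 5 of 9 mast cell and basophil, 7 of 12 carcinoma, 7 of 13 B and plasma cell and 11 of 16 neutrophil genes. Results of these lists cover those members at most.

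The genes named were also fixed by a rule before the data were examined. The rule takes Pik3cg, then up to 8 genes higher and 8 lower with the largest absolute log2 fold change among those called, with a group mean of at least 5 CPM and no overlap between the genotypes. It adds up to 4 members of each list described, those with the smallest p, the panel Arg1, Il10, Tgfb1, Il12b, Il1b, Il6, Tnf, Nos2, Ifng, Cd274, H2-Aa, H2-Ab1, Gzmb and Cd8a, and the 5 genes in each direction with the smallest adjusted p for the difference of the genotype effects. Not every list member that the rule allows is named, and some results are not reported. Genes named outside the rule are said to be chosen after their values were seen.

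The fits were tested on simulated data with changes of 0.5, 1 and 2 on the log2 scale. The simulated noise was drawn for each gene on its own, and genes with a low mean were left unchanged. For the fits without the block, it lacked the structure shared by same-numbered libraries. The shares and false calls below may therefore not hold for the real libraries. In the TAM design (12395 genes), 16.7%, 65.7% and 92.5% of the changed genes were called, with 5 false calls. With the block (12455 genes), the shares were 43.9%, 82.1% and 92.5%, with 7 false calls. In the whole tumor design (12696 genes), they were 56.1%, 91.0% and 97.0%, with 7 false calls. For the difference of the genotype effects (12807 genes), they were 13.6%, 49.3% and 73.1%, with 7 false calls. Alternatives tried before or after seeing the data were a median-ratio rescaling of the libraries, no filter, sample quality weights, the block, all 14 libraries in a single fit, pseudocounts of 0.5 and 8, an estimated correlation for the lists, leaving out each library in turn, and leaving out both TAM libraries of a number. All sample columns of both tables were used.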

Results

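The data were gene-level RNA values from 14 libraries of LLC flank tumors in 4 groups: 4 TAM libraries and 3 whole tumor libraries from WT mice, and as many of each from p110g-/- mice. The normalized counts summed to 33248294 to 38153438 per TAM library and 25883561 to 27586429 per whole tumor library. The estimated depth was 26.8 to 40.7 M reads in the WT TAM, 19.7 to 40.2 M in the p110g-/- TAM, 41.5 to 44.6 M in the WT tumors and 32.1 to 43.4 M in the p110g-/- tumors. The share of mitochondrial genes was 2.49% to 3.32% in whole tumors. In TAM libraries 1 to 4 it was 2.51%, 3.06%, 7.70% and 9.59% in WT and 2.73%, 3.21%, 9.01% and 14.4% in p110g-/-.

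Pik3cg, the targeted gene, was measured first in every library. WT TAM libraries 1 to 4 held 3745, 4477, 3070 and 2748 normalized counts, and the p110g-/- TAM held 2203, 2211, 1210 and 1401. All 4 p110g-/- libraries were thus below every WT library, at a ratio of means of 0.50 (log2 fold change −1.02, SE 0.24, adjusted p = 0.299 with limma, and 0.00557 with the block). Whole tumors held 487, 616 and 527 in WT and 242, 279 and 417 in p110g-/- (log2 fold change −0.83, SE 0.19, adjusted p = 0.0555). That adjusted p was 0.0488 without p110g-/- tumor 1 and 0.0445 without p110g-/- tumor 3. The part of the gene removed by the targeting is not given in the sources used here, and where in the gene the remaining reads lie was not analysed here.

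The comparison of p110g-/- with WT TAM addressed what loss of PI3K gamma does to the expression of sorted tumor macrophages. Without the block, 14 genes passed the test, 2 of them from the type I interferon response list. With the block 312 passed, 19 of them from that list. The genes named next passed in both fits. Ifi44 (gene ID 99899), an interferon-induced gene, fell from 269 ± 42.1 to 38.5 ± 12.7 normalized counts (SD, n = 4 and 4; log2 fold change −2.81, SE 0.25, adjusted p = 0.00773). Bst2 (69550), which encodes the antiviral membrane protein tetherin, fell from 4454 ± 320 to 2336 ± 338 (log2 fold change −0.94, SE 0.11, adjusted p = 0.0302). Lyz1 (17110), a lysozyme gene, rose from 3044 ± 506 to 20111 ± 5826 (log2 fold change 2.69, SE 0.21, adjusted p = 0.00496). H60b (667281) and Raet1e (379043), which encode ligands of the activating receptor NKG2D, rose from 26.0 ± 7.48 to 225 ± 121 and from 485 ± 66.9 to 1903 ± 622.

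Other genes called in TAM had varied functions. Hdac9 (79221), a class IIa histone deacetylase gene, fell from 541 ± 143 to 101 ± 27.5 normalized counts (log2 fold change −2.41, SE 0.26, adjusted p = 0.0215). Epb4.1l1 (13821), of the band 4.1 family of membrane skeleton proteins, fell from 3717 ± 270 to 2182 ± 194. Klrb1b (80782), a C-type lectin receptor gene of the NKR-P1 family, rose from 588 ± 35.3 to 1579 ± 213. Cacna1a (12286), a voltage-gated calcium channel subunit gene, rose from 23.3 ± 5.56 to 178 ± 36.0. Gfra2 (14586), a co-receptor of the GDNF family, rose from 56.3 ± 9.64 to 271 ± 69.7, and Sbsn (282619), suprabasin, from 111 ± 13.9 to 283 ± 42.6. The remaining 3 called genes were below the CPM minimum of the naming rule and were chosen after their values were seen. Zfp781 (331188) was listed at 0 in all 4 WT libraries and held 46 to 54 normalized counts in p110g-/-, Hddc3 (68695) rose from 21.8 ± 3.59 to 139 ± 48.4, and Apol9b (71898) fell from 89.5 ± 13.9 to 11.3 ± 3.50.

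Among the 12475 genes tested in TAM, limma called 9 higher and 5 lower in p110g-/-, and 732 had an unadjusted p under 0.05. With the block, 126 were higher and 186 lower, all 14 genes of the fit without it among them. In 537 genes, 4.30%, the libraries of the genotypes did not overlap, against 2.86% by chance. All 14 libraries in a single fit gave 45 higher and 38 lower, and sample quality weights 654 and 345. Leaving out a library changed these counts, to 33 higher and 7 lower without WT 1, 3 and 0 without WT 2, 4 and 1 without WT 3, and 4 and 2 without WT 4. They were 13 and 26 without p110g-/- 1, 4 and 3 without p110g-/- 2, 5 and 1 without p110g-/- 3, and 4 and 1 without p110g-/- 4. The calls of Lyz1, Klrb1b and Zfp781 held without each library. That of Ifi44 ended without WT 2 (adjusted p = 0.074), those of Cacna1a without WT 2 or p110g-/- 4 (highest adjusted p = 0.0631), and the others without several libraries. In the authors' deposited table for TAM, pp was above 0.95 for 283 genes, 282 of them tested, of which 14 were called here and 261 with the block.

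The type I interferon response list fell in p110g-/- TAM. All 20 tested members were lower, with a median log2 fold change of −1.61, and all 20 were lower in each of the 4 same-numbered pairs (adjusted p = 1.2e-35, and adjusted p = 0.221 with an estimated correlation). Over all genes 2 members were called, Ifi44 and Bst2, and 19 when adjusted over the list alone. With the block, 19 were called lower over all genes and 20 adjusted over the list alone. Isg15, a ubiquitin-like interferon-induced protein, was at 2057 ± 549 in WT and 686 ± 207 in p110g-/- (adjusted p = 0.0683, and 9.6e-04 with the block), and Oasl1, of the oligoadenylate synthetase family, at 1517 ± 507 and 385 ± 112 (adjusted p = 0.0683, and 0.00105 with the block). Without p110g-/- 1 both passed the test (adjusted p = 0.0206 and 0.0394). The MHC class I presentation list also fell, by a median of −0.22, with 13 of 14 members lower (adjusted p = 1.0e-04, and adjusted p = 0.801 with an estimated correlation). None of its members was called over all genes or adjusted over the list alone, while the block called 9 adjusted over the list alone and 2 over all genes, Nlrc5 (log2 fold change −0.57, adjusted p = 0.047) and Tap1 (−0.39, adjusted p = 0.0388). H2-M3 and Psmb10 had log2 fold changes of −0.34 and −0.28. This list was no longer called without WT 1 (adjusted p = 0.0579).

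The immediate-early and dissociation stress list rose in p110g-/- TAM, with all 20 members higher and a median log2 fold change of 0.44 (adjusted p = 3.9e-13, and adjusted p = 0.221 with an estimated correlation). No member was called over all genes and 7 when adjusted over the list alone, and the block called 6 over all genes and 12 adjusted over the list alone. Fosb, a subunit of the AP-1 transcription factor, was at 2150 ± 893 normalized counts in WT and 7794 ± 1902 in p110g-/- (adjusted p = 0.101, and 0.0298 with the block). The transcription factor gene Egr1 was at 3424 ± 486 and 5957 ± 1160, and Dusp1, a MAP kinase phosphatase gene, at 13622 ± 5144 and 26697 ± 4134 (adjusted p with the block 0.0213 and 0.0279). The NF-kB inflammatory targets rose by a median of 0.40, with 15 of 20 members higher (adjusted p = 1.8e-05, and adjusted p = 0.599 with an estimated correlation), none of them called over all genes or adjusted over the list alone. The block called 5 adjusted over the list alone and 3 over all genes, Ptgs2 (log2 fold change 0.80, adjusted p = 0.0132), chosen after its values were seen, and the neutrophil chemokine genes Cxcl2 (log2 fold change 1.91, adjusted p = 0.0172) and Cxcl1 (1.55, adjusted p = 0.047), and Cxcl2 passed the test without the block when WT 1 was left out (adjusted p = 0.019). Tnfaip3, an inhibitor of NF-kB signalling, was at 1550 ± 517 in WT and 3105 ± 627 in p110g-/-. These libraries also differed in the mitochondrial share, which averaged 5.72% ± 3.48 in WT and 7.34% ± 5.51 in p110g-/- and was above 7% in libraries 3 and 4 of both genotypes.

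A further 3 lists passed the test in TAM by a small margin. The immune-suppressive and alternative activation list rose by a median of 0.22, with 15 of 24 members higher (adjusted p = 0.0333, 0.0708 with the block, and adjusted p = 0.801 with an estimated correlation). Its leading member was Pdcd1lg2, which encodes PD-L2, at 64.8 ± 24.0 in WT and 191 ± 38.0 in p110g-/- (adjusted p = 0.154, and 0.0474 with the block), the only member called when adjusted over the list alone, with none over all genes. The block called it over all genes and 2 members adjusted over the list alone. Socs3 (log2 fold change 0.66), Il1rn (0.67) and Mgl2 (0.94) followed, and Pdcd1lg2 was called without WT 1 (adjusted p = 0.0267) and Mgl2 without p110g-/- 1 (adjusted p = 0.0159). Neutrophil markers rose by a median of 0.39, with 7 of 8 tested members higher and none called over all genes or adjusted over the list alone (adjusted p = 0.0339, and adjusted p = 0.798 with an estimated correlation), led by Il1r2 (821 ± 198 and 1432 ± 483) and Hdc (59.3 ± 27.2 and 134 ± 92.9). With the block, 3 of these were called adjusted over the list alone and none over all genes. Fibroblast and matrix markers fell by a median of −0.93, with 20 of 21 members lower and none called over all genes or adjusted over the list alone (adjusted p = 0.0439, 9.8e-09 with the block, and adjusted p = 0.827 with an estimated correlation). With the block, 14 members were called lower adjusted over the list alone and 1 over all genes, Sparc (adjusted p = 0.0149), chosen after its values were seen. Dcn, decorin, was at 2120 ± 1491 and 1322 ± 1188. Without p110g-/- 1 the fibroblast median was 0.16 and the call was lost, as it was without WT 2, WT 3, WT 4 or p110g-/- 2 (highest adjusted p = 0.708). It was kept when both libraries numbered 1 were left out (fibroblast and matrix markers list, TAM p110g-/- vs WT: median −0.79, adjusted p = 0.0027). The suppressive list was not called without WT 2, WT 3, WT 4 or p110g-/- 4 (highest adjusted p = 0.24), nor the neutrophil list without WT 2, WT 3, WT 4, p110g-/- 1 or p110g-/- 4 (highest adjusted p = 0.216). With 1 library left out, the median was 0.066 to 0.44 for the suppressive list and 0.29 to 0.81 for the neutrophil list.

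**Figure D1:**
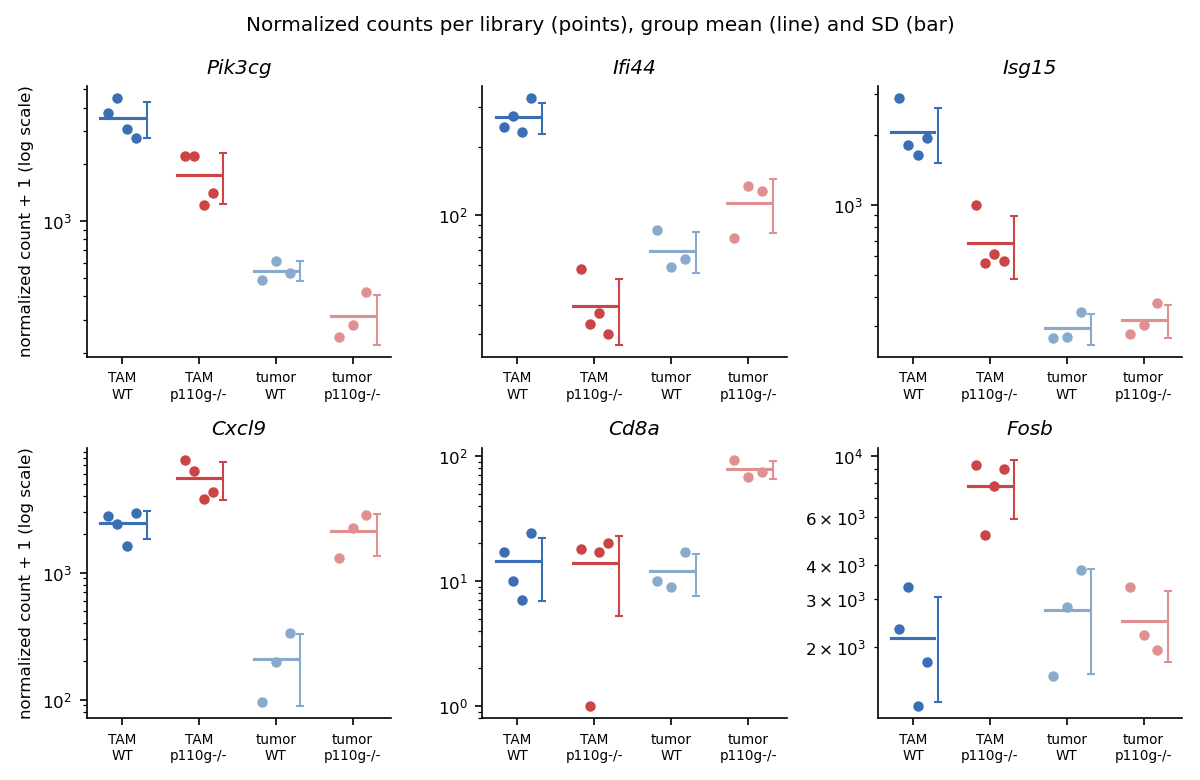
Normalized counts plus 1 on a log axis for 6 genes in the 4 groups, with points for libraries, a line for the group mean and a bar for the SD. Ifi44 and Isg15 lie lower in every p110g-/- TAM library than in any WT TAM library, and Cd8a and Cxcl9 lie higher in every p110g-/- tumor than in any WT tumor.

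Macrophage markers as a list did not differ between the genotypes in TAM (adjusted p = 0.560, median log2 fold change 0.01), but single members and other genes of macrophage function did with the block. Cd14, a co-receptor for bacterial lipopolysaccharide, was at 17192 ± 6464 normalized counts in WT and 58539 ± 11422 in p110g-/- (adjusted p = 0.0621, and 0.0135 with the block). Fcgr1, an Fc receptor gene, was at 11141 ± 3701 and 7109 ± 2512 (adjusted p = 0.824, and 0.0103 with the block). The monocyte marker Ly6c2 was at 692 ± 483 and 170 ± 101 (0.360, and 0.00604 with the block), and Plac8 at 2008 ± 1628 and 949 ± 1023 (0.999, and 0.00805 with the block). For Plac8, WT 1 held 4450 against 1163 to 1229 in the other WT libraries, and p110g-/- 1 held 2481 against 364 to 486. Cd36, a scavenger receptor for lipids, was at 2117 ± 1095 and 6079 ± 2298 (0.307, and 0.0101 with the block), and the T cell chemokine gene Cxcl9 at 2453 ± 600 and 5570 ± 1830 (0.291, and 0.0149 with the block). Cd36 and Cxcl9 were chosen after their values were seen. Without WT 1, Cd14 passed the test in the fit without the block (adjusted p = 0.00815).

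No gene of the fixed panel passed the test in TAM, with or without the block. Arg1, arginase 1, was at 63691 ± 64377 normalized counts in WT, where WT 1 alone held 160107, and at 64548 ± 8164 in p110g-/-. Nos2, the inducible nitric oxide synthase gene, was at 525 ± 292 and 988 ± 256 (log2 fold change 1.01, adjusted p = 0.641), and Il1b at 7393 ± 2164 and 12574 ± 5645 (0.70, adjusted p = 0.870). H2-Aa and H2-Ab1, of MHC class II, had log2 fold changes of 0.17 and 0.17. They were 0.30 for Tnf, 0.84 for Il6, 0.24 for Cd274, −0.11 for Tgfb1, −0.39 for Il10, −0.17 for Il12b, −0.52 for Gzmb and −0.56 for Cd8a. Each of these genes had an adjusted p of 0.999. Cd8a was listed at 0 in p110g-/- 2, where 3 reads would be 3.43 normalized counts. Ifng, at 2.75 ± 2.75 in WT and 3.75 ± 2.06 in p110g-/-, was below the minimum and was not tested.

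The other lists did not pass the test in TAM. Their adjusted p was 0.626 for PI3K class I subunits, 0.138 for MHC class II presentation, 0.393 for immune-stimulating mediators, 0.336 for the interferon-gamma response, 0.223 for chemokines for monocytes and neutrophils, 0.306 for monocytes, 0.153 for dendritic cells, 0.424 for T cells, 0.141 for cytotoxic and NK cells, 0.438 for B and plasma cells and 0.996 for endothelium. It was 0.369 for carcinoma epithelium, 0.136 for keratinocytes, 0.228 for skeletal muscle, 0.560 for adipocytes, 0.619 for erythroid cells, 0.939 for hypoxia and glycolysis, 0.324 for angiogenic factors, 0.669 for oxidative phosphorylation, 0.138 for ribosomal proteins, 0.196 for cholesterol synthesis and 0.303 for lysosome and lipid handling. Proliferation had 23 of 24 members higher (adjusted p = 0.277, 0.0176 with the block, and with the block adjusted p = 0.678 with an estimated correlation). Its mean log2 level was higher in p110g-/- in pair 1 (9.33 and 10.03) and pair 2 (11.07 and 11.21) but lower in pair 3 (10.76 and 10.70) and pair 4 (10.83 and 10.61). Mast cell and basophil markers had too few tested members. The test and the mean had opposite signs for PI3K subunits, and the test and the median for carcinoma markers.

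The comparison of whole p110g-/- tumors with WT tumors addressed the tumor as a whole, with its immune, stromal and carcinoma cells. Among the genes that rose most were members of the interferon-gamma response, T cell and cytotoxic lists. Cxcl9 (gene ID 17329), a chemokine gene induced by interferon-gamma, rose from 209 ± 121 to 2129 ± 773 normalized counts (SD, n = 3 and 3; log2 fold change 3.45, SE 0.45, adjusted p = 0.0142). Cd8a (12525), the co-receptor of cytotoxic T cells, rose from 11 ± 4.36 to 77.3 ± 13.1 (log2 fold change 2.75, SE 0.29, adjusted p = 0.00823), and Ifng (15978), interferon-gamma itself, from 4.33 ± 4.04 to 39.0 ± 6.00 (log2 fold change 3.15, SE 0.50, adjusted p = 0.0243). The GTPase genes Tgtp1 (21822; 35.7 ± 18.2 to 382 ± 112), Tgtp2 (100039796; 69.0 ± 27.2 to 493 ± 99.6), Iigp1 (60440; 170 ± 42.2 to 1287 ± 376), Gbp4 (17472; 92.7 ± 35.4 to 644 ± 219), Gbp5 (229898; 102 ± 43.7 to 551 ± 151), Gbp6 (100702; 128 ± 15.3 to 781 ± 219) and Gm4951 (240327; 23.7 ± 1.15 to 155 ± 42.4) rose in parallel.

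Other genes fell in p110g-/- tumors. Il1a (16175), interleukin 1 alpha, fell from 1074 ± 300 to 337 ± 131 normalized counts (log2 fold change −1.70, SE 0.29, adjusted p = 0.0282). Osm (18413), oncostatin M, fell from 4291 ± 1375 to 1960 ± 334, and Csf2ra (12982), the alpha chain of the GM-CSF receptor, from 1883 ± 425 to 759 ± 164. Tnnt2 (21956), cardiac troponin T, fell from 144 ± 51.7 to 25.7 ± 8.62. Nrep (27528) fell from 336 ± 163 to 76.7 ± 6.11, and Fam20c (80752), a kinase of secreted proteins, from 477 ± 72.2 to 156 ± 27.4. Scand1 (19018) fell from 259 ± 53.5 to 111 ± 33.4 and Dmp1 (13406), a mineralized matrix protein gene, from 147 ± 32.4 to 64.3 ± 14.4.

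Among the 12717 genes tested in whole tumor, limma called 286 higher and 267 lower in p110g-/-, and 3332 had an unadjusted p under 0.05. All 14 libraries in a single fit gave 13 and 2, and sample quality weights 1154 and 1154. The genotypes' libraries did not overlap in 3946 genes, 31%, against 10% by chance. The counts depended on single libraries: 51 higher and 35 lower without WT 1, 24 and 7 without WT 2, 106 and 49 without WT 3, 980 and 1021 without p110g-/- 1, 21 and 8 without p110g-/- 2, and 34 and 35 without p110g-/- 3. Of the genes named, the calls of Iigp1, Tgtp2, Gm4951, Gbp2, Gbp3, Gbp6 and Fam20c held without each library. Those of Cd8a and Tgtp1 ended only without p110g-/- 2 (adjusted p = 0.051 and 0.0519), that of Krt8 only without WT 2 (adjusted p = 0.0505), and the others without at least 2 libraries, p110g-/- 2 or p110g-/- 3 among them. In the authors' deposited table for whole tumor, pp was above 0.95 for 141 genes, of which 113 were called here.

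Lists of interferon response and of MHC class I presentation rose in p110g-/- tumors. Of the 18 genes of the interferon-gamma response, 17 were higher, by a median of 1.62, and 15 were called over all genes and 15 adjusted over the list alone (adjusted p = 3.0e-16, and adjusted p = 0.562 with an estimated correlation). Gbp2, a guanylate-binding protein gene, rose from 911 ± 217 to 3960 ± 752 normalized counts and Gbp3 from 227 ± 24.8 to 818 ± 173. All 14 members of MHC class I presentation were higher, by a median of 0.48, with 12 called over all genes and 13 adjusted over the list alone (adjusted p = 1.6e-12, and adjusted p = 0.562 with an estimated correlation). They included the immunoproteasome subunit gene Psmb9 (288 ± 45.8 to 657 ± 68.4), the class I transactivator gene Nlrc5 (504 ± 97.7 to 1224 ± 168), the peptide transporter gene Tap1 (763 ± 135 to 1656 ± 198) and B2m, the light chain (25112 ± 1940 to 37104 ± 914). The type I interferon response list rose by a smaller median of 0.28, with 18 of 20 members higher, 1 called over all genes and 5 adjusted over the list alone (adjusted p = 3.6e-04, and adjusted p = 0.819 with an estimated correlation). With 1 library left out, its median was 0.17 to 0.44. The antiviral synthetase gene Oas3 (log2 fold change 0.64), Oas2 (0.76) and Stat2 (0.44) did not pass the test over all genes. These 3 passed it without p110g-/- 1 (adjusted p = 0.0112, 0.0147 and 0.00884).

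Lymphocyte lists rose as well. All 19 tested T cell markers were higher in p110g-/- tumors, by a median of 1.38, with 8 called over all genes and 18 adjusted over the list alone (adjusted p = 4.0e-10, and adjusted p = 0.562 with an estimated correlation). Beside Cd8a, these included Cd8b1, its partner chain (10.3 ± 3.21 to 35.3 ± 11.4 normalized counts), Cd3d of the T cell receptor complex (28 ± 9.17 to 69.7 ± 11) and the adaptor gene Sh2d2a (52.7 ± 16 to 138 ± 22.1). Of 16 cytotoxic and NK markers 15 were higher, by a median of 1.59, with 7 called over all genes and 15 adjusted over the list alone (adjusted p = 8.1e-09, and adjusted p = 0.562 with an estimated correlation). The granule protein gene Nkg7 rose from 36.3 ± 10.7 to 131 ± 17.8, perforin (Prf1) from 41.7 ± 6.81 to 146 ± 45.3, and the chemokine gene Xcl1 from 18 ± 7.55 to 68.0 ± 24.3. B and plasma cell markers were not called (adjusted p = 0.413, median log2 fold change 0.21), nor were macrophage markers (adjusted p = 0.214, median 0.11).

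Stromal and growth-related lists were called in whole tumor too. All 14 endothelial markers were higher in p110g-/-, by a median of 0.55, with none called over all genes and 7 adjusted over the list alone (adjusted p = 7.7e-05, and adjusted p = 0.646 with an estimated correlation). Kdr, a VEGF receptor gene, was at 104 ± 30.9 normalized counts in WT and 174 ± 13.5 in p110g-/-, and Pecam1 at 398 ± 102 and 596 ± 67.3. All 20 cytosolic ribosomal protein genes were lower, by a median of −0.22, with Rpl11 called over all genes and 16 adjusted over the list alone (adjusted p = 2.6e-08, and adjusted p = 0.562 with an estimated correlation). Oxidative phosphorylation fell by a median of −0.13, with 19 of 21 members lower, none called over all genes and 9 adjusted over the list alone (adjusted p = 2.0e-05, and adjusted p = 0.562 with an estimated correlation). Proliferation fell by a median of −0.11, with 22 of 24 members lower and Ccnb2, cyclin B2, called over all genes and adjusted over the list alone (adjusted p = 0.00175, and adjusted p = 0.837 with an estimated correlation). This call was lost without p110g-/- 3 (adjusted p = 0.198), and with 1 library left out the proliferation median was −0.19 to −0.029.

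Another 3 lists of whole tumor had an adjusted p near the threshold. Neutrophil markers rose by a median of 0.65, led by Csf3r, the G-CSF receptor gene (1273 ± 249 to 2124 ± 479 normalized counts in the p110g-/- tumors), with no member called over all genes or adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.819 with an estimated correlation). Adipocyte markers rose by a median of 0.45, with no member called over all genes and 2 adjusted over the list alone (adjusted p = 0.036, and adjusted p = 0.562 with an estimated correlation), and cholesterol synthesis fell by a median of −0.14, with 15 of 18 members lower and none called (adjusted p = 0.036, and adjusted p = 0.837 with an estimated correlation). The neutrophil call was lost without WT 1, WT 3, p110g-/- 1 or p110g-/- 3 (highest adjusted p = 0.166), the adipocyte call without WT 3 or p110g-/- 3 (highest adjusted p = 0.0825), and the cholesterol call without WT 1, WT 2, p110g-/- 2 or p110g-/- 3 (highest adjusted p = 0.413).

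**Figure D2:**
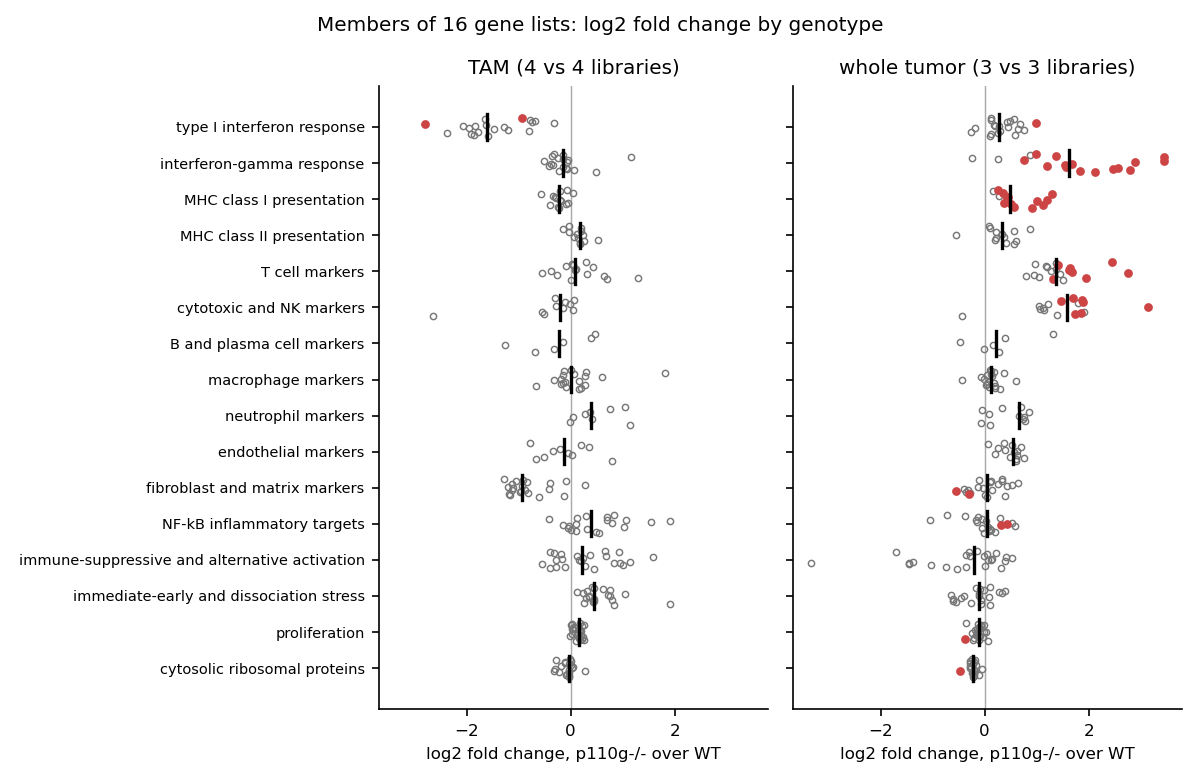
Log2 fold change, p110g-/- over WT, of the tested members of 16 gene lists in TAM (left) and whole tumor (right), with red filled points for members with an adjusted p below 0.05 over all genes and a black line for the list median. The type I interferon response median is −1.61 in TAM and 0.28 in whole tumor, and the interferon-gamma response median is −0.15 and 1.62.

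Of the fixed panel, Cd8a, Ifng and Nos2 rose in p110g-/- tumors, Nos2 from 705 ± 102 to 1837 ± 524 normalized counts (log2 fold change 1.35, SE 0.19, adjusted p = 0.0186). Gzmb, granzyme B, was at 117 ± 40.2 in WT and 310 ± 106 in p110g-/- (log2 fold change 1.39, adjusted p = 0.0549) and passed the test without p110g-/- 1 (adjusted p = 0.0182). Arg1 was at 16463 ± 4737 and 11158 ± 1966 (−0.54, adjusted p = 0.141), Tgfb1 at 2639 ± 273 and 2052 ± 281 (−0.37, adjusted p = 0.0923) and Cd274, which encodes PD-L1, at 1144 ± 265 and 1611 ± 145 (0.52, adjusted p = 0.107). Il10 (0.32), Il12b (−0.52), Il1b (−0.13), Il6 (−0.72), Tnf (−0.38), H2-Aa (0.56) and H2-Ab1 (0.41) did not pass the test either, with adjusted p from 0.275 for Il6 to 0.772 for Il1b. Il6 passed it without p110g-/- 1 (adjusted p = 0.0481).

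Carcinoma epithelial markers were not called as a list (adjusted p = 0.0562), although the keratin genes Krt8 (7717 ± 171 to 5003 ± 416 normalized counts) and Krt18 (6561 ± 373 to 4817 ± 244) fell in p110g-/- tumors. The other adjusted p in whole tumor were 0.0562 for mast cells and basophils, 0.0875 for the suppressive and alternative activation list, 0.265 for PI3K class I subunits, 0.260 for MHC class II presentation, 0.428 for immune-stimulating mediators, 0.395 for NF-kB targets, 0.910 for chemokines for monocytes and neutrophils, 0.827 for monocytes, 0.265 for dendritic cells and 0.645 for fibroblasts and matrix. They were 0.131 for keratinocytes, 0.444 for skeletal muscle, 0.233 for erythroid cells, 0.827 for hypoxia and glycolysis, 0.444 for angiogenic factors, 0.220 for immediate-early and dissociation stress and 0.265 for lysosome and lipid handling. The test and the median had opposite signs for the chemokine, monocyte and fibroblast lists, and the test and the mean for the chemokine, fibroblast and angiogenic lists. In the suppressive list, Ccl17 was at 78.0 ± 87.4 in WT and 4.00 ± 1.00 in p110g-/- (adjusted p = 0.0518), Ccl22, another ligand of the receptor CCR4, at 228 ± 149 and 72.0 ± 13.9 (adjusted p = 0.0965), and Tgfb2 at 131 ± 19.9 and 78.3 ± 19.1 (adjusted p = 0.0741). Ccl17 passed the test without WT 1 (adjusted p = 0.0459).

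Whether the genotype effect differed between TAM and whole tumor was tested as the effect in TAM minus that in whole tumor. The interferon-induced genes Ifi44 (difference −3.50, SE 0.38, adjusted p = 0.00875) and Apol9b (−2.95, SE 0.35, adjusted p = 0.011) had a lower effect in TAM. So did Iigp1 of the interferon-gamma response list (−2.97, SE 0.42, adjusted p = 0.027), the immunoproteasome gene Psmb9 (−1.39, SE 0.20, adjusted p = 0.027) and Ccnd2, cyclin D2 (−0.93, SE 0.13, adjusted p = 0.027). Iigp1 was at −0.07 in TAM and 2.89 in whole tumor. Raet1e (1.96, SE 0.28), Gfra2 (2.04, SE 0.31), Cacna1a (1.98, SE 0.32), Ptgfrn (1.44, SE 0.21) and Rgs18, a regulator of G protein signalling (1.63, SE 0.25), had a higher effect in TAM, with adjusted p from 0.027 to 0.0321. Rgs18 was at −0.21 in TAM and −1.84 in whole tumor. Of 12821 genes, limma called 5 with a higher and 13 with a lower effect in TAM, and 835 had an unadjusted p under 0.05. With the block these counts were 55 and 280, although same-numbered libraries were alike only in the TAM, and with sample quality weights 897 and 995. Without WT tumor 2 or p110g-/- tumor 2 limma called no gene in either direction. The counts higher and lower were 0 and 1 without WT tumor 1, 0 and 7 without WT tumor 3, 0 and 3 without p110g-/- tumor 1, and 1 and 2 without p110g-/- tumor 3. Among the TAM, they were 13 and 22 without WT TAM 1, 0 and 4 without WT TAM 2, 5 and 16 without WT TAM 3, 0 and 2 without WT TAM 4, 16 and 79 without p110g-/- TAM 1, 4 and 8 without p110g-/- TAM 2, 2 and 5 without p110g-/- TAM 3, and 1 and 2 without p110g-/- TAM 4. The call of Ifi44 ended only without WT tumor 2 or p110g-/- tumor 2 (highest adjusted p = 0.0566). That of Apol9b ended without these or WT tumor 1 (highest 0.0585), and the others without at least 8 of the 14 libraries (highest 0.128).

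The lists with the largest differences in genotype effect were those of interferon and lymphocytes. The median difference, TAM minus whole tumor, was −1.81 for the interferon-gamma response (adjusted p = 1.3e-22), −1.78 for the type I interferon response (adjusted p = 2.7e-34), −0.73 for MHC class I presentation (adjusted p = 2.8e-22), −1.87 for cytotoxic and NK cells (adjusted p = 1.5e-13) and −1.35 for T cells (adjusted p = 3.4e-09). Of the 16 cytotoxic and 19 T cell members, 10 and 15 were tested in TAM and the others lay below the minimum there, so for those members the difference rests on the whole tumors. It was 0.75 for immediate-early genes (adjusted p = 2.6e-10), 0.36 for the suppressive list (adjusted p = 0.00195), 0.27 for NF-kB targets (adjusted p = 0.0332), 0.27 for proliferation, −0.65 for endothelium and 0.093 for oxidative phosphorylation (adjusted p = 0.0438 each). With an estimated correlation limma's camera called none of these, with adjusted p from 0.115 for the type I interferon and MHC class I lists upward.

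Across 12486 genes the genotype effects in TAM and in whole tumor showed little correlation, with Pearson's r = 0.0848 (exact permutation p = 0.8) and Spearman's rho = 0.126 (exact permutation p = 0.6). The smallest p that the 70 labelings allow is 0.0286. These labelings ignore the library numbers, which can widen the range of r. The permutation therefore does not decide whether the effects agree. Without p110g-/- TAM 1, r was −0.0446. Among genes tested in both, Cacna1a, H60b and Hddc3 were called higher in both, against 0.195 by chance, and Hdac9 was called lower in both, against 0.105. In the p110g-/- tumors H60b had a log2 fold change of 1.17 (adjusted p = 0.0319), Cacna1a of 0.91 (adjusted p = 0.0293), Hddc3 of 1.67 (adjusted p = 0.0219) and Hdac9 of −1.24 (adjusted p = 0.0413).

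The levels in WT libraries describe what the sort enriched, though the tables may have been scaled separately and the levels were not tested. Of 19 macrophage markers, 18 were higher in WT TAM than in WT tumors, by a median of 2.71 on the log2 scale. All 13 MHC class II genes were higher by a median of 2.97, and all 20 type I interferon genes by a median of 3.08. All 21 fibroblast and matrix markers were lower in TAM, by a median of −2.52, as were neutrophil (−3.67), endothelial (−1.97) and erythroid (−6.25) markers by the median. B and plasma cell (0.66) and carcinoma epithelial (0.67) markers were higher in TAM by the median. Fibroblast and matrix genes also differed between TAM libraries of different numbers. Their mean log2 level in libraries 1 to 4 was 6.15, 8.96, 9.91 and 10.2 in WT and 5.01, 7.70, 9.73 and 9.54 in p110g-/-.

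**Figure D3:**
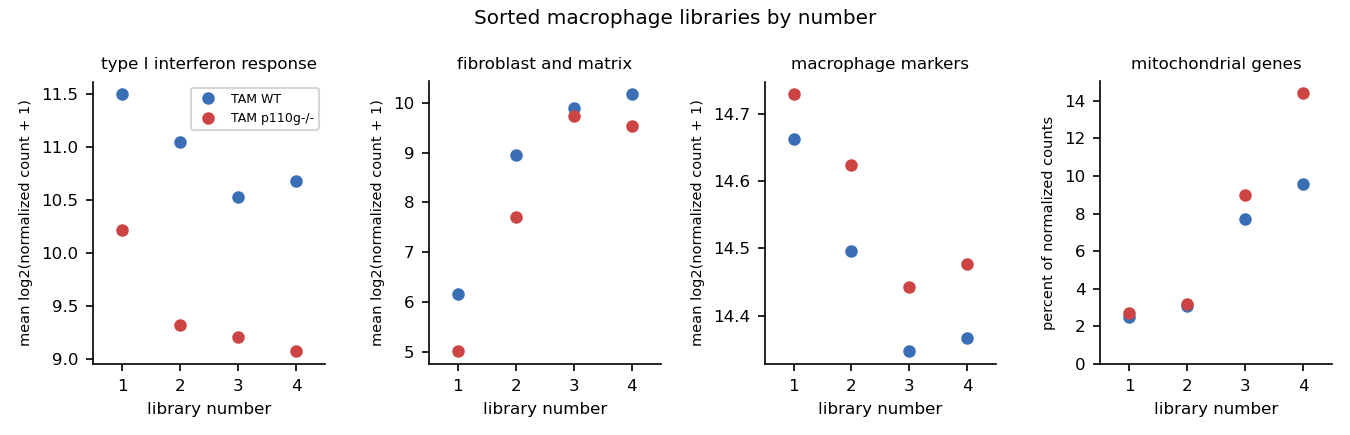
TAM libraries by their number, WT in blue and p110g-/- in red, with the mean log2(normalized count + 1) of the type I interferon, fibroblast and macrophage lists and the percent of normalized counts from mitochondrial genes. In every pair of the same number the type I interferon list lies lower in p110g-/-, and the fibroblast level and the mitochondrial share are higher in libraries 3 and 4 than in 1 and 2 in both genotypes.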

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

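The tests for other cell types in the sorts, for the share of tumor cells, for lymph node tissue and for reads shared with Lyz2 were chosen after the results were seen. In groups of 4 TAM libraries, a value was singled out when its gap to the nearest other, as a share of the range of the group, was above Dixon's 95% critical value. This held in 15 of 128 groups tested, where chance gives about 6.4, and 10 of the 15 were TAM WT 1. TAM WT 1 held 160107 normalized counts of Arg1, 12963 of Cxcl2, 10864 of Nfkbia, 16633 of Fcgr1, 1415 of Ly6c2, 4450 of Plac8, 10625 of Il1b, 72 of Il6, 4479 of Cd274 and 1116 of Il1r2, each above the other 3 WT libraries. TAM p110g-/- 1 held 994 of Isg15 and 2481 of Plac8, above the other 3, and 879 of Mgl2, below them. TAM p110g-/- 2 held 24 of Gzmb and 0 of Cd8a, below the other 3.

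The genotype effect differed between TAM and whole tumor, by the test of the difference, for 10 genes named by the rule. It was lower in TAM for Ifi44 (−3.50), Iigp1 (−2.97), Apol9b (−2.95), Psmb9 (−1.39) and Ccnd2 (−0.93), and higher for Gfra2 (2.04), Cacna1a (1.98), Raet1e (1.96), Rgs18 (1.63) and Ptgfrn (1.44). By the same test it differed for 11 lists, with medians of −1.87 for cytotoxic and NK cells, −1.81 for the interferon-gamma response, −1.78 for the type I interferon response, −1.35 for T cells, −0.73 for MHC class I presentation, −0.65 for endothelium, 0.75 for immediate-early genes, 0.36 for the suppressive list, 0.27 for NF-kB targets, 0.27 for proliferation and 0.093 for oxidative phosphorylation. With an estimated correlation limma's camera called none of these (lowest adjusted p = 0.115). Of 100 splits drawn without regard to the pairs, 3 called as many genes as the 18 of the real one (highest other 2182), a share under 0.05, and the highest count points to a structure of the samples other than genotype. For the lists, 63 of 100 splits called as many as the 11 of the real one (highest other 21), so chance is not excluded for their number.

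For the type I interferon response list, lower in p110g-/- TAM, lower depth of the p110g-/- libraries was tested by thinning. With all TAM libraries thinned to the 19.7 M reads of the shallowest, the list median in the same-numbered pair closest to 0 was still −1.33. All members had TAM group means of at least 38.5 normalized counts, far above 3 reads, so thinning could move this median little. Without thinning, pairs 1 and 2, of nearly equal depth (40.7 and 40.2 M, 31 and 29.9 M in WT and p110g-/-), had medians of −1.34 and −1.90. More cells of other types in the p110g-/- sorts would lower macrophage genes alike, but the list median minus the macrophage list median was −1.27 in the pair closest to 0. A different mix or handling of the sorted cells stays open. In every same-numbered pair the fibroblast list was lower and the mitochondrial share higher in p110g-/-. With the block, Ly6c2 and Plac8 fell and stress genes rose. An effect of PI3K gamma loss on interferon signalling in these cells, or on the interferon they meet in the tumor, is another hypothesis that was not tested. The number of lists called in TAM does not exclude chance, since 27 of 35 splits of the 8 libraries called as many as the 7 of the real one (highest other 17).

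T cell and cytotoxic lists were higher in whole p110g-/- tumors, where a lower share of tumor cells would raise the markers of every other cell type alike, but the T cell and cytotoxic score rose over the macrophage score by 1.36 (SE 0.24), and over the neutrophil score by 1.04 (SE 0.42, libraries overlapping). A lower share as part of the cause stays open, since the carcinoma score was −0.30 and the endothelial and neutrophil scores 0.49 and 0.44. Of 5 carcinoma members compared between the WT groups, 3 were higher in TAM than in whole tumors, so that score does not track tumor cells alone. Lymph node tissue in the pieces would bring B cells, but the T cell score rose over the B cell score by 1.19 (SE 0.13). Lymph node tissue is not excluded by this, as only 6 of the 13 fixed B and plasma cell genes were tested. Of 7 compared between the WT groups, 5 were higher in TAM than in whole tumors, so the score does not track B cells alone. More T and NK cells in p110g-/- tumors may explain it, as may a higher expression of these genes per cell, which was not tested. The 10 splits of the 6 libraries are too few for a share under 0.05, with 553 genes called in the real split (1 of 10) and 0 in the highest other, and 12 lists in the real split against 23 in the highest other (8 of 10 called as many).

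Single genes were called in p110g-/- TAM. A donor-strain segment carried along with the targeted gene would hold them. However, only 1 of the 14 called genes, Hdac9, lay within 100 tested genes of Pik3cg. For strain differences between the colonies at other places, called genes beside each other were counted. There were 2 (H60b and Raet1e) within 25 tested genes of each other, as many as in 2748 of 10000 random sets. This cannot be told apart from chance, and a strain difference that altered 1 gene alone would leave no called neighbour. The count therefore does not decide whether strain differences play a part. For Hdac9 itself, 7 tested genes from Pik3cg, a donor-strain segment around the targeted gene cannot be told apart from another cause, because genes around Pik3cg were called more often than elsewhere in TAM with the block (5.56% against 2.43%, Fisher's exact p = 0.0142, the interferon-induced Rsad2 and Cmpk2 among them) but not by the test in TAM without it (1 of 180, p = 0.185) or in whole tumor (4.44% against 4.21%, p = 0.851). A constant share of Lyz2 reads counted as Lyz1 would move these genes together. The log2 ratio of Lyz1 to Lyz2 instead rose by at least 1.81 in every pair. A share of reads that differed between the genotypes is not excluded by this. Chance is not excluded for the number of genes, as 2 of 35 splits called as many as the real 14, the other being libraries 1 and 2 against 3 and 4, with 2638, which points to a structure by number, and among the 8 splits that part all 4 pairs the block called 312 in the real one (1 of 8) and at most 3 in the others, too few splits for a share under 0.05.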

How the results depend on the processing

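The pseudocounts (except 0.5 for the correlation of the effects, which was planned), the block for Pik3cg and the leaving out of both TAM libraries of a number were chosen after seeing the data. Median-ratio rescaling, no filter and pseudocounts of 0.5 and 8 kept the counts of genes called within 1.5 times. In TAM (9 higher, 5 lower), sample quality weights called 654 higher and 345 lower, the block 126 and 186, all 14 libraries in a single fit 45 and 38, and leaving out both libraries numbered 1 gave 72 and 61. With the block and without both libraries numbered 1, 2, 3 or 4, the counts were 298 and 313, 28 and 50, 24 and 67, and 32 and 66. Leaving out 1 library gave 3 to 33 higher and 0 to 26 lower. With the block Pik3cg in TAM (−1.02, adjusted p = 0.00557) passed the test. The 7 lists called in TAM became 0 with an estimated correlation, 5 with no filter, 11 with the block and without both libraries numbered 2, and 4 to 12 when 1 library was left out. In whole tumor (286 and 267), weights called 1154 and 1154, and all 14 libraries in a single fit 13 and 2. Leaving out 1 library gave 21 to 980 higher and 7 to 1021 lower. Same-numbered whole tumors correlated at 0.068, 0.089 and 0.200, so they share only a number. The block there called 439 and 320, among them all 141 genes with pp above 0.95 in the authors' deposited table, and Pik3cg (−0.83, adjusted p = 0.0456) passed the test. Without 1 library Pik3cg in whole tumor was −1.05 to −0.66. The 12 lists called there became 0 with an estimated correlation. For the difference of the genotype effects (5 and 13), weights called 897 and 995, the block 55 and 280, and leaving out 1 library gave 0 to 16 and 0 to 79. The correlation of the effects was −0.0446 to 0.118 when 1 library was left out. Values that changed sign were Cd8a in TAM with weights (0.56) and, with 1 library left out, in TAM Il12b (−0.60 to 0.22), Krt8 (−1.59 to 0.35), Il10 (−0.90 to 0.049), H2-Aa (−0.0099 to 0.28), H2-Ab1 (−0.016 to 0.27), Cd8a (−0.95 to 0.49), Tgfb1 (−0.25 to 0.011) and the fibroblast list (−1.90 to 0.16), and in whole tumor Il10 (−0.018 to 0.61), H2-Ab1 (−0.041 to 0.93), Il1b (−0.37 to 0.081), Zfp781 (−1.90 to 2.28) and Isg15 (−0.016 to 0.23). For all of these the cause was not tested. Beyond the TAM values given with the block in the report, the block changed the call of no other named TAM gene of the fixed panel and of no other list. Over all alternatives, the TAM genes followed kept direction and side of the threshold in 792 cases, passed it in 67, no longer passed it in 60 and changed sign in 9, and the whole tumor genes followed did so in 751, 39, 203 and 8. The DESeq2 alternative was not run, since it needs raw counts, nor were alternatives for a test of TAM against whole tumor, which was not made. Sample weights were estimated on the limma fit in place of voom, and their estimation stopped before its tolerance in 2 fits. Depth limits low genes, with 3 reads at up to 5.81 normalized counts in TAM and 2.48 in whole tumor.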

Other observations

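The genes named here were chosen after their values were seen. Of 12396 genes tested in both, 18 were called lower in TAM with the block and higher in whole tumor, against 4.01 by chance. Among them were the MHC class I genes H2-Q4, H2-Q6, H2-Q7, H2-T9, H2-T10 and H2-T24, the presentation genes Tap1 and Nlrc5, and the interferon-induced genes Ifi47, Zbp1, Parp12, Parp14, Trim30a, Uba7 and Tnfsf10. In the other direction, higher in TAM and lower in whole tumor, there were 2 genes, Ephx1 and Ptgfrn, against 2.63 by chance. Called higher in both were 15 genes, among them Cxcl9, Kit and the Langerhans cell lectin gene Cd207, against 2.71 by chance. Called lower in both were 11 genes, among them the interferon-induced gene Ifi27l2a, against 3.90 by chance. These figures by chance take genes as independent, which genes of a shared response are not. The values of the H2-Q and H2-T genes are also uncertain, as given above. Without the block, where 5 genes were called lower in TAM, 0 of these were called higher in whole tumor, against 0.11 by chance.

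Some genes were called in p110g-/- tumors although their list was not. The receptor gene Kit (log2 fold change 0.85), from the mast cell list, the NF-kB targets Birc3 (0.44) and Vcam1 (0.32), the haptoglobin gene Hp (0.81), the chemokine gene Cx3cl1 (0.59) and the glycolysis regulator gene Pfkfb3 (0.54) were higher, and the collagen genes Col6a2 (−0.56) and Col5a1 (−0.31) and the angiogenin gene Ang (−1.02) were lower, with adjusted p from 0.0251 for Col6a2 to 0.0488 for Kit. Zfp781, listed at 0 in WT TAM, held 70, 0 and 71 normalized counts in WT tumors and 0, 68 and 100 in p110g-/- tumors, so it did not follow genotype there.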
